A study of Rattus norvegicus with 16 samples.

How the data were processed

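Poly(A) RNA from rat liver was sequenced after library preparation with a stranded mRNA kit, per the labels' protocols. The 16 libraries fall into 4 groups of 4 by genotype (wild type or Tspo knockout) and diet (chow or MCD), per the labels, which also give each library its number. The series title speaks of mice, while the organism label of every sample is rat. No label names a sequencing batch, and read length, strand setting and gene annotation are not given in the sources used here.

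The first table holds expected counts per gene, which the authors made with RSEM; the submitters' processing notes name RSEM 1.2.15, Bowtie2 2.1.0 and the rn6 build, without their roles. Expected counts share reads among genes they fit equally well, so single values of close copies (the Cyp2c, sulfotransferase, glutathione transferase and hemoglobin families) are uncertain. Of the values 88.9% were whole numbers. The second table holds a normalised signal in CPM of the library total times a TMM factor, as deposited by the authors. Each of its 202017 values above 0 equalled the rounded count times 1 constant per library, within a relative tolerance of 1e-06, and its columns sum to 752514 to 1546939. Both tables have 17168 genes, named by symbol. Of these symbols 14504 match a symbol of the RefSeq table of assembly GRCr8 and another 2242 match a synonym. That assembly differs from rn6, so it served for names only, and no coordinates are given. The table's Scd1 is the gene now called Scd and its Scd is the gene now called Scd2.

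Library totals ran from 8745756 to 15762660 counts. Pairs of libraries within a group differed by a chi-square per gene of 15.3 to 383.9 over genes with at least 20 counts, so none is a repeat of another. Reads without molecular identifiers are not independent molecules, and the Poisson intervals given for Tspo (95%) cover counting error only.

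Counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 4 groups, which left 11162; 2844 genes were at 0 in all libraries. TMM factors, a design with 1 term per group, robust dispersions (common biological coefficient of variation 28%, 12 residual degrees of freedom) and the robust quasi-likelihood test were used. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a contrast. The 5 contrasts were MCD minus chow in each genotype, knockout minus wild type on each diet, and the difference of the diet effects. Log2 CPM values have a prior count of 2. TMM left the median gene at 0.03 (wild type) and 0.057 (knockout) on the log2 scale between diets, and unscaled values put it at 0.549 and 0.759; upper quartile factors gave 0.071 and 0.161. All changes are therefore relative to the bulk of genes.

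Gene lists were tested with camera from limma 3.58.1, with a preset correlation of 0.01, for 29 lists in 5 contrasts and adjusted over the 145 tests. The lists cover cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, lipid droplets, lipoproteins, bile acids, methionine and choline metabolism, matrix and stellate cells, macrophages, lymphocytes, neutrophils, cytokines, interferon, acute phase, hepatocyte functions, bile duct cells, endothelium, NRF2 targets, stress responses, cytochromes P450, cell cycle, oxidative phosphorylation, TSPO partners, heme synthesis, the clock, immediate early genes, red blood cells, neighbouring pancreas and fat, and sex-biased genes. With the correlation estimated from the data 0 of the 145 tests were called, and with fry, which tests whether a list's genes move one way on balance, 20 were. All 20 were for the diet, 8 in the wild type and 12 in the knockout. Fry called 0 lists in either knockout contrast and 0 in the difference of the diet effects. For each list the number of members past the threshold is given over all genes and adjusted over the list alone. The groups, contrasts, tests, lists, the rule for named genes and most alternatives were fixed before the data were examined.

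Genes named in the text are Tspo in each contrast, up to 10 called genes per direction with the largest log2 fold (the smallest p in the interaction), and per list up to 4 called members with the smallest p, or 2 members where none was called. The first of these needed a level of at least 5 CPM in the higher group, a real gene symbol and no overlap between the libraries of the groups. Not all genes so chosen are described. Levels and no folds are given for Stac3, Mmp12 and Phgdh, because folds fitted to so few counts in a group depend on the prior count.

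The scripts were tested on simulated data with the real means, library sizes and dispersions of 11162 genes. The added changes were put in the knockout on MCD alone. Simulated libraries of a group differed only by library size and independent draws, so none stood apart as some real libraries did. In the knockout contrast on MCD edgeR recovered 57 of 100 genes changed 2-fold and 92 of 100 changed 4-fold, with 7 unchanged genes called. In the interaction it recovered 17 and 67 of 100, with 4 unchanged genes called, and in the knockout contrast on chow, where nothing was changed, it called 0.

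The alternatives were DESeq2 1.42.0, RLE and upper quartile factors, no filter, a filter of 1 CPM in 8 libraries, a fit of the compared groups alone, and a test against an absolute log2 fold of 0.5. Further ones were limma-trend on the deposited signal with pseudocounts of 1 and 0.25, a block on the library number, number 4 as a batch or left out in all groups, and each of the 16 libraries left out in turn. Chosen after seeing the data were fits without knockout chow library 4 and knockout MCD library 1, without both chow libraries numbered 4, without all 3 of these, voom with library weights, and a fit with the long minus short index as a covariate. Residuals of libraries with the same number in different groups correlated above 0.1 in 7 of 24 pairs, with the own number the best match in 4, so the numbers were not treated as pairs; the chow libraries numbered 4 did resemble each other (r = 0.511). The reads themselves were not analysed here.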

Results

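Liver RNA was sequenced from Sprague Dawley rats labelled wild type or Tspo knockout, which were fed either ordinary chow or a methionine- and choline-deficient (MCD) diet. Tspo encodes the translocator protein of the outer mitochondrial membrane, which binds cholesterol. The MCD diet removes nutrients needed to make phosphatidylcholine and export fat, and is used to induce steatohepatitis, a fatty liver with inflammation. The diet started at 12 weeks of age and lasted 8 weeks, so the animals were 20 weeks old at sampling. There were 4 groups of 4 libraries each, 16 libraries in all, named below by genotype, diet and the number in their label. Total counts per library were 8745756 to 12896860 for the wild type on chow, 11330051 to 12521173 for the knockout on chow, 10931121 to 15762660 for the wild type on MCD and 10749769 to 15347830 for the knockout on MCD. Levels are given in CPM, counts relative to the library total scaled by TMM factors, as mean ± SD with n = 4 libraries per group. Changes are given as log2 fold ± SE with adjusted p-values, the fold and p-value from edgeR. The SE was derived as the absolute log2 fold over the square root of the F statistic of the quasi-likelihood test. The labels do not say whether the 4 libraries of a group came from separate animals, so the p-values measure the spread between these libraries.

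Tspo was the targeted gene and was examined first. On chow its level was 4.25 ± 0.728 CPM in the wild type and 1.87 ± 1.72 CPM in the knockout. On the MCD diet it was 8.42 ± 0.779 CPM in the wild type and 2.02 ± 1.46 CPM in the knockout. In 6 of the 8 libraries labelled knockout Tspo lay between 0.66 and 1.66 CPM, from counts of 6 to 29. The library labelled knockout on chow number 4 had 4.42 CPM (95% Poisson interval 3.041 to 6.204), inside the range of 3.61 to 5.23 CPM of the chow-fed wild type. The library labelled knockout on MCD number 1 had 4.17 CPM (3.184 to 5.37), below the range of 7.63 to 9.34 CPM of the MCD-fed wild type. These intervals cover counting error only. The part of Tspo removed in the knockout is not given in the sources used here, so counts per gene may include reads from a part left in place. Tspo therefore lay at a wild-type level in the former and between the genotypes in the latter, and every direction given below for the knockout rests on groups that include them. With all libraries the log2 fold of knockout over wild type was -1.23 ± 0.49 (adjusted p = 0.46) on chow and -2.07 ± 0.45 (adjusted p = 1) on MCD, the latter with an unadjusted p of 0.00029. Without the library labelled knockout on chow number 4 the chow value was -2.04 (adjusted p = 0.247). With both doubtful libraries left out, a choice made after seeing the data, the values were -2.04 (adjusted p = 0.0107) on chow and -2.68 (adjusted p = 0.000135) on MCD. These libraries were doubted for their high Tspo, so leaving them out widens its difference by construction. The adjusted p-values without them are thus no independent evidence. Between diets, Tspo in the wild type differed by 0.98 ± 0.44 (adjusted p = 0.093), which did not pass the threshold.

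**Figure D1:**
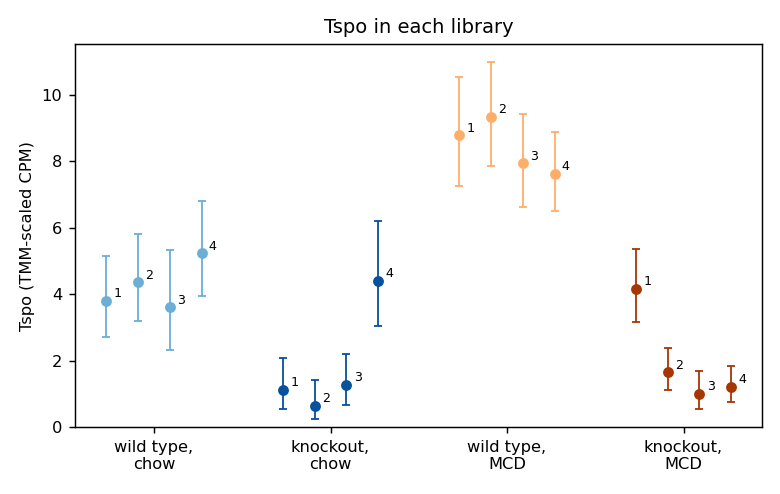
Tspo in TMM-scaled CPM (vertical axis) in each library, by group, with the library number beside each point and 95% Poisson intervals of the count as bars. The libraries labelled knockout lie between 0.66 and 1.66 CPM except number 4 on chow at 4.42 CPM and number 1 on MCD at 4.17 CPM.

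The first principal component of log2 CPM held 55.2% of the variance and parted the diets. The second held 16.1% and set apart 3 libraries, at -33 for the wild type on chow number 4, -63.7 for the library labelled knockout on chow number 4 and -44.2 for the library labelled knockout on MCD number 1, against -9.1 or more in the other 13. The same 3 libraries stood apart in an index of long minus short transcripts, the mean log2 CPM of 21 genes with long messages minus that of 25 genes with short ones. The index was -0.72, -1.85 and -0.76 in them, -0.16 to 0.37 in the other chow libraries and 1.21 to 1.94 in the other MCD libraries, relative to the wild type on chow. Unequal loss of long messages is one sign of RNA quality, so each list call that was lost with the index in the model is given below.

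**Figure D2:**
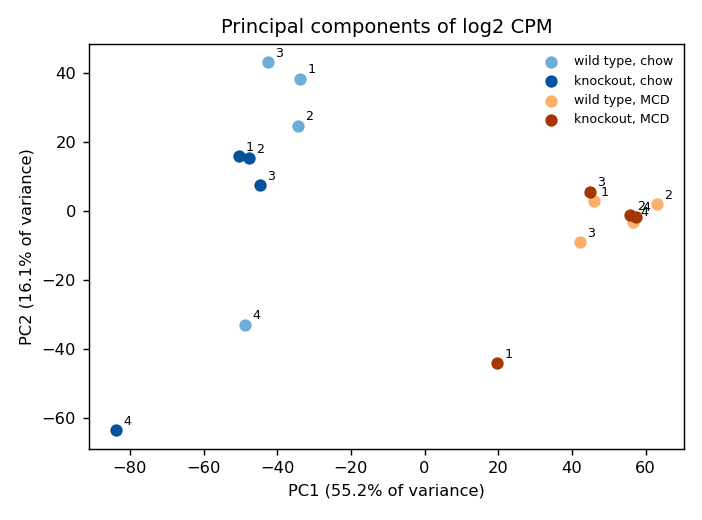
First and second principal components of log2 CPM for the 16 libraries, coloured by group, with the share of variance on each axis and the library number beside each point. Diet lies along the first component, and the second sets apart the chow libraries numbered 4 (-33 and -63.7) and number 1 of the knockout on MCD (-44.2).

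The first comparison asked what the MCD diet did to the wild-type liver. Secreted and metabolic products of hepatocytes fell (14 of 24 listed genes), including transthyretin and insulin-like growth factor 1, and so did lipoprotein genes (11 of 19) such as Apoc1 and Apoc3. Genes of DNA replication and mitosis rose (21 of 26), as did Gpnmb, a marker of lipid-laden macrophages, and Epcam, a marker of bile duct cells. The list of 21 macrophage genes was not called as a group, with 6 up and 2 down (camera adjusted p = 0.237). Hemoglobin and other red cell transcripts (7 of 7) and drug-metabolising cytochromes P450 (15 of 27) fell. In total 3809 of 11162 genes changed, 2031 upward and 1778 downward, and 1932 of them at least 2-fold.

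Among single genes, Abcb1b, a multidrug efflux pump of the canalicular membrane, rose from 2.86 ± 1.25 to 270.5 ± 166 CPM, a log2 fold of 6.56 ± 0.48 (adjusted p = 3.85e-07). Mmp12, the macrophage metalloelastase, rose from 0.725 ± 0.552 to 42.6 ± 20.1 CPM, and Gpnmb, a glycoprotein of lipid-laden macrophages, rose from 7.79 ± 1.15 to 185 ± 71.2 CPM. Stac3, an adaptor protein best known from muscle excitation-contraction coupling, fell from 323 ± 78.0 to 0.222 ± 0.0446 CPM (adjusted p = 1.14e-10). The prolactin receptor Prlr fell from 55.0 ± 22.1 to 1.62 ± 1.00 CPM, and Cyp2c7 from 5689 ± 1518 to 173 ± 17.6 CPM. Sult2a1, a sulfotransferase of bile acids and steroids, fell from 1422 ± 1027 CPM, with 2961 CPM in wild-type chow library 4 and 840.3 to 952.6 CPM in the other 3, to 46.3 ± 18.7 CPM. Cyp2c, sulfotransferase and hemoglobin genes have close copies, and reads shared among them make their single values uncertain.

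Of 24 measured hepatocyte function genes 14 fell and 0 rose (15 and 0 adjusted over the list alone; camera adjusted p = 2.27e-06, adjusted p = 0.102 with an estimated correlation). Igf1, the growth factor released under growth hormone, fell from 1855 ± 744 to 262 ± 17.2 CPM, and its carrier subunit Igfals had a log2 fold of -2.08 ± 0.21 (adjusted p = 6.22e-06). Transthyretin (Ttr), the thyroid hormone carrier, fell from 15690 ± 3320 to 4022 ± 1337 CPM, and the gluconeogenic enzyme Fbp1 from 600.3 ± 53.4 to 222 ± 22.6 CPM. Of 19 lipoprotein genes 11 fell and 1 rose (13 and 1 adjusted over the list alone; adjusted p = 5.97e-07, adjusted p = 0.111 with an estimated correlation). Apoc3, which inhibits clearance of triglyceride-rich particles, had a log2 fold of -2.85 ± 0.27 (adjusted p = 3.67e-06), and Lcat, which esterifies cholesterol in high-density lipoprotein, one of -1.50 ± 0.18 (adjusted p = 2.50e-05). Of 27 cytochromes P450 15 fell and 4 rose (16 and 5 adjusted over the list alone; adjusted p = 0.000124, adjusted p = 0.49 with an estimated correlation). Cyp2c23 fell from 1038 ± 123 to 197 ± 79.2 CPM, and Cyp2d3 and Cyp2d4 also fell.

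Of 26 cell cycle genes 21 rose and 0 fell (22 and 0 adjusted over the list alone; adjusted p = 9.6e-12, adjusted p = 0.195 with an estimated correlation). Tyms, the thymidylate synthase, rose from 2.15 ± 0.227 to 9.59 ± 0.843 CPM and the mitotic cyclin Ccnb1 from 1.19 ± 0.652 to 6.48 ± 0.440 CPM. Of 31 matrix and stellate cell genes 9 rose and 1 fell, the same counts as adjusted over the list alone (adjusted p = 0.00948, adjusted p = 0.747 with an estimated correlation). Timp1, an inhibitor of matrix breakdown, rose by 2.13 ± 0.29 (adjusted p = 6.97e-05), Ctgf, a profibrotic growth factor, by 2.28 ± 0.36 (adjusted p = 0.000279), and the stellate cell gene Reln by 1.49 ± 0.29 (adjusted p = 0.00131). This list's call was lost without the wild-type MCD library number 2 (adjusted p = 0.124) or the wild-type chow library number 4 (adjusted p = 0.0646), and with the long minus short index in the model (adjusted p = 0.619). Of 12 bile duct and ductular reaction genes 5 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.0169, adjusted p = 0.567 with an estimated correlation, 0.072 with the index in the model, 0.055 without both chow libraries numbered 4, 0.0942 without the 3 libraries that stood apart). Epcam, a surface protein of bile duct cells, rose by 1.35 ± 0.17 (adjusted p = 3.75e-05), and Spp1 (osteopontin) from 3.74 ± 2.64 to 51.8 ± 31.4 CPM.

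All 7 red blood cell genes fell, also adjusted over the list alone (adjusted p = 2.43e-07, adjusted p = 0.189 with an estimated correlation), with Hba1 going from 575 ± 119 to 62.3 ± 31.7 CPM. Of 24 nuclear genes of oxidative phosphorylation 9 fell and 1 rose (10 and 1 adjusted over the list alone; adjusted p = 0.00948, adjusted p = 0.747 with an estimated correlation). Cox5b, a subunit of cytochrome c oxidase, fell from 191 ± 40.9 to 102 ± 14.4 CPM. The list was no longer called with the index in the model (adjusted p = 0.643), but the short genes of the index include other subunits of the same complexes, so for this list, in each comparison, the lost call says little about message length. The 3 sex-biased genes fell, also adjusted over the list alone (adjusted p = 0.0354, adjusted p = 0.424 with an estimated correlation, 0.0592 without the wild-type chow library number 4, 0.221 with the index in the model), among them Obp3, an odorant-binding protein of male rat liver, from 2376 ± 1219 to 297 ± 200.5 CPM. Obp3 was not called with the index in the model (adjusted p = 0.0907).

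Other lipid and methionine lists held genes moving both ways and were not called. Of 18 fatty acid synthesis genes 3 rose and 6 fell (3 and 7 adjusted over the list alone; adjusted p = 0.331). Scd1, the stearoyl-CoA desaturase, fell from 2014 ± 825 to 231 ± 112 CPM and the lipogenic regulator Thrsp from 722 ± 142 to 246 ± 93.3 CPM. Of 23 cholesterol synthesis and uptake genes 8 rose and 2 fell (11 and 3 adjusted over the list alone; adjusted p = 0.23). Of 27 methionine, one-carbon and choline genes 6 rose and 7 fell (7 and 9 adjusted over the list alone; adjusted p = 0.437). Psat1 of serine synthesis rose by 2.73 ± 0.34 (adjusted p = 3.91e-05) and Mat2a, which makes S-adenosylmethionine, by 2.38 ± 0.31 (adjusted p = 5.39e-05). Cbs, which draws homocysteine into cysteine synthesis, fell from 218 ± 58.1 to 42.1 ± 13.1 CPM. Of 27 fatty acid oxidation genes 5 rose and 9 fell (6 and 9 adjusted over the list alone; adjusted p = 0.683), with the regulator Ppara rising by 2.08 ± 0.26 (adjusted p = 4.47e-05). Of 16 lipid droplet genes 2 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.835). The fatty acid carrier Fabp4 rose from 2.98 ± 0.802 to 36.8 ± 16.5 CPM, and the triglyceride lipase Pnpla2 from 40.6 ± 6.69 to 72.9 ± 5.01 CPM.

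A test against an absolute log2 fold of 0.5 called 1593 genes, and 10 of the 35 splits of these 8 libraries into 4 and 4 gave at least the 9 lists called here. With the long minus short index in the model, an alternative chosen after seeing the data, 2077 of the 3809 genes (54.5%) were called as well.

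The second comparison asked the same of the knockout. Hepatocyte (15 of 24), lipoprotein (12 of 19) and red cell genes (7 of 7) fell here too, and genes of cell division (22 of 26), bile duct cells (5 of 12) and matrix (17 of 31) rose. Fatty acid synthesis genes fell (8 of 18), with Scd1, Thrsp and Pnpla3 among them. In total 4514 genes changed, 2447 upward and 2067 downward, and 2433 of them at least 2-fold.

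Of 18 fatty acid synthesis genes 8 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.000284, adjusted p = 0.493 with an estimated correlation). Scd1 went from 5729 ± 1645 to 157 ± 41.2 CPM, a log2 fold of -5.19 ± 0.44 (adjusted p = 1.20e-06). Pnpla3, a lipase and acyltransferase of lipid droplets, went from 375 ± 229.5 to 6.17 ± 4.03 CPM, and Thrsp from 1516 ± 408 to 191 ± 47.8 CPM. Of 24 hepatocyte function genes 15 fell (16 adjusted over the list alone; adjusted p = 4.35e-07, adjusted p = 0.102 with an estimated correlation), with Igfals at -2.35 ± 0.21 (adjusted p = 2.11e-06). Of 19 lipoprotein genes 12 fell and 1 rose (13 and 1 adjusted over the list alone; adjusted p = 8.87e-06, adjusted p = 0.189 with an estimated correlation), with Apoc1 going from 4451 ± 1419 to 739 ± 326 CPM. Of 27 cytochromes P450 14 fell and 4 rose (16 and 4 adjusted over the list alone; adjusted p = 0.000524, adjusted p = 0.493 with an estimated correlation). Cyp2e1, which oxidises ethanol and fatty acids, was among those that rose, from 721 ± 239 to 3204 ± 604 CPM. All 7 red blood cell genes fell, also adjusted over the list alone (adjusted p = 3.71e-07, adjusted p = 0.211 with an estimated correlation).

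Of 26 cell cycle genes 22 rose (23 adjusted over the list alone; adjusted p = 9.6e-12, adjusted p = 0.211 with an estimated correlation), with Mcm6, part of the replicative helicase, at 2.65 ± 0.35 (adjusted p = 5.42e-05). Of 31 matrix and stellate cell genes 17 rose and 0 fell (19 and 0 adjusted over the list alone; adjusted p = 0.000304, adjusted p = 0.743 with an estimated correlation, 0.0795 with the index in the model). Timp1 rose by 2.31 ± 0.30 (adjusted p = 4.34e-05), and Acta2, the smooth muscle actin of activated stellate cells, from 1.68 ± 1.08 to 6.81 ± 3.19 CPM. The latter level was near that of the chow-fed wild type, given in the third comparison. The rise in Acta2 thus started from a low level in the chow-fed knockout. Acta2 was not called with the index in the model (adjusted p = 0.137). Of 12 bile duct genes 5 rose (6 adjusted over the list alone; adjusted p = 0.0121, adjusted p = 0.49 with an estimated correlation, 0.0569 without the libraries labelled knockout on chow number 4 and on MCD number 1). Of 24 oxidative phosphorylation genes 13 fell and 1 rose (15 and 1 adjusted over the list alone; adjusted p = 0.00086, adjusted p = 0.699 with an estimated correlation, 0.0795 with the index in the model). Phgdh, the first enzyme of serine synthesis, rose from 0.873 ± 0.600 to 26.5 ± 5.76 CPM. A test against an absolute log2 fold of 0.5 called 2176 genes. With the index in the model 2886 were called, of which 2254 were among the 4514 (49.9%).

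Both genotypes were then set side by side. Of the called genes 3052 moved the same way in both, 1665 upward and 1387 downward, where independent lists of these sizes would share 445 and 329. Of the 11162 genes 0 were called in opposite directions (at most 29 in any alternative where this was counted). In the wild type but not the knockout 757 were called, and 1462 in the knockout but not the wild type. Across genes, which are not independent replicates, the log2 folds had a Pearson correlation of 0.895 and a Spearman correlation of 0.880. Abcb1b (6.56 and 5.85), Gpnmb (4.57 and 4.05), Apoc3 (-2.85 and -2.59) and Timp1 (2.13 and 2.31) had similar log2 folds in the wild type and the knockout.

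**Figure D3:**
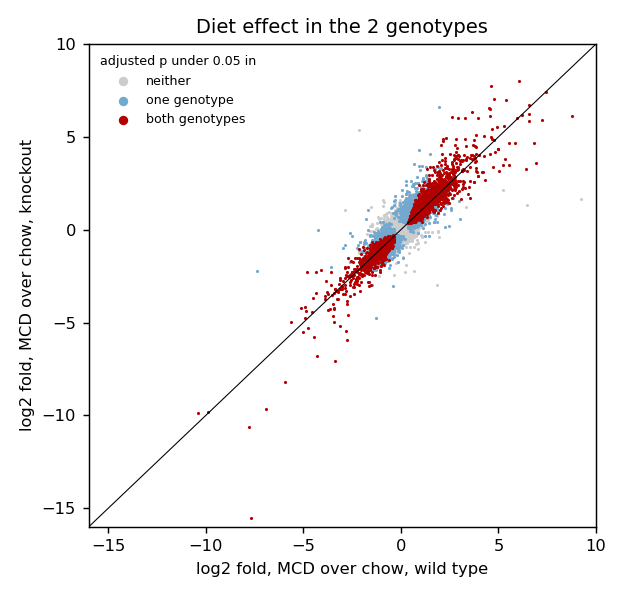
Log2 fold of MCD over chow for 11162 genes in the wild type (horizontal axis) and the knockout (vertical axis), with a line of equality and colours for genes past the threshold in no genotype, a single genotype or both. The 3052 genes called in both lie on the same side of 0 in each.

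The third comparison asked what the loss of Tspo did on chow. Fatty acid synthesis genes were higher as a group in the knockout, and matrix and stellate cell genes lower (camera adjusted p = 2.16e-07 and 1.59e-05; adjusted p = 0.213 and 0.699 with an estimated correlation), but no single member of either list passed the threshold over all genes. The only gene that did, of 11162, was LOC500124, a placeholder symbol, which fell from 10.3 ± 2.21 to 4.08 ± 0.620 CPM (-1.32 ± 0.18 (adjusted p = 0.0191)). It lies outside the rule for named genes and was chosen after its values were seen. At an unadjusted p under 0.05 there were 1153 genes, where 558 would be expected by chance.

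Of 18 fatty acid synthesis genes 16 had positive log2 folds, with a median of 0.52, and 0 were called over all genes and 6 upward adjusted over the list alone (camera adjusted p = 2.16e-07, adjusted p = 0.213 with an estimated correlation). Acly, which makes cytosolic acetyl-CoA, was at 365 ± 125 CPM in the wild type and 869 ± 249 CPM in the knockout (1.25 ± 0.30 (adjusted p = 0.395)). Pnpla3 was at 53.9 ± 37.3 and 375 ± 229.5 CPM (2.80 ± 0.69 (adjusted p = 0.395)), with 383.2 to 563.2 CPM in knockout libraries 1 to 3 and 50.06 CPM in number 4. Of 31 matrix and stellate cell genes 6 had log2 folds above 0, with 0 called and 2 downward adjusted over the list alone (adjusted p = 1.59e-05, adjusted p = 0.699 with an estimated correlation). Acta2 was at 5.89 ± 1.52 and 1.68 ± 1.08 CPM (-1.79 ± 0.48 (adjusted p = 0.395)), and Tagln, another contractile protein gene, at 13.9 ± 4.48 and 5.97 ± 3.46 CPM. The matrix mean was lowest in knockout chow library 4 (-0.96) and wild-type chow library 4 (-0.45) of their groups, as was the long minus short index (-1.85 and -0.72); in libraries 1 to 3 the index was -0.16 to 0.09 in the knockout and 0.14 to 0.37 in the wild type.

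Another 5 lists were called upward with 0 members past the threshold over all genes. Oxidative phosphorylation genes had an adjusted p of 0.00264 (adjusted p = 0.726 with an estimated correlation, 0 adjusted over the list alone). The mean of this list was 0.68 in knockout chow library 4 against 0.01 to 0.23 in the other 3. Short transcripts were higher too (median 0.45, adjusted p = 0.00627, adjusted p = 0.68 with an estimated correlation). Their mean was 1.45 in knockout chow library 4, against -0.14 to 0.11 in the other 3 and -0.35 to 0.41 in the wild type. Stress response genes had 0.0118 (adjusted p = 0.601 with an estimated correlation), lost without knockout chow library 3 (0.0871) or wild-type chow library 4 (0.276), and interferon genes 0.0163 (adjusted p = 0.747 with an estimated correlation), lost without wild-type chow library 3 (0.55) or knockout chow library 3 (0.0782). Fatty acid oxidation genes had 0.0204 (adjusted p = 0.726 with an estimated correlation), lost without wild-type chow library 3 (0.227) or knockout chow library 1 (0.124). Heme synthesis genes had 0.0251 (adjusted p = 0.49 with an estimated correlation), lost without wild-type chow library 4 (0.0632) or knockout chow library 4 (0.122). Of these 4 lists only the interferon list had a member called adjusted over the list alone, 1 upward.

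The count of 1 gene by edgeR depended on the libraries and the tool. It was 15 without wild-type chow library 4 and 0 without wild-type chow library 1, 2 or 3 or knockout chow library 2, 3 or 4. DESeq2 called 23 genes and limma-trend 2, and without the 3 libraries that stood apart, a choice made after seeing the data, edgeR called 514, 203 upward and 311 downward. On 513 of these 514 genes wild-type chow library 4 lay at 0.931 on a scale from wild type (0) to knockout (1) in chow libraries 1 to 3. That library also stood apart in other ways, so whether these genes follow genotype or other differences among the libraries cannot be told. Their number is therefore no measure of the loss of Tspo.

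**Figure D4:**
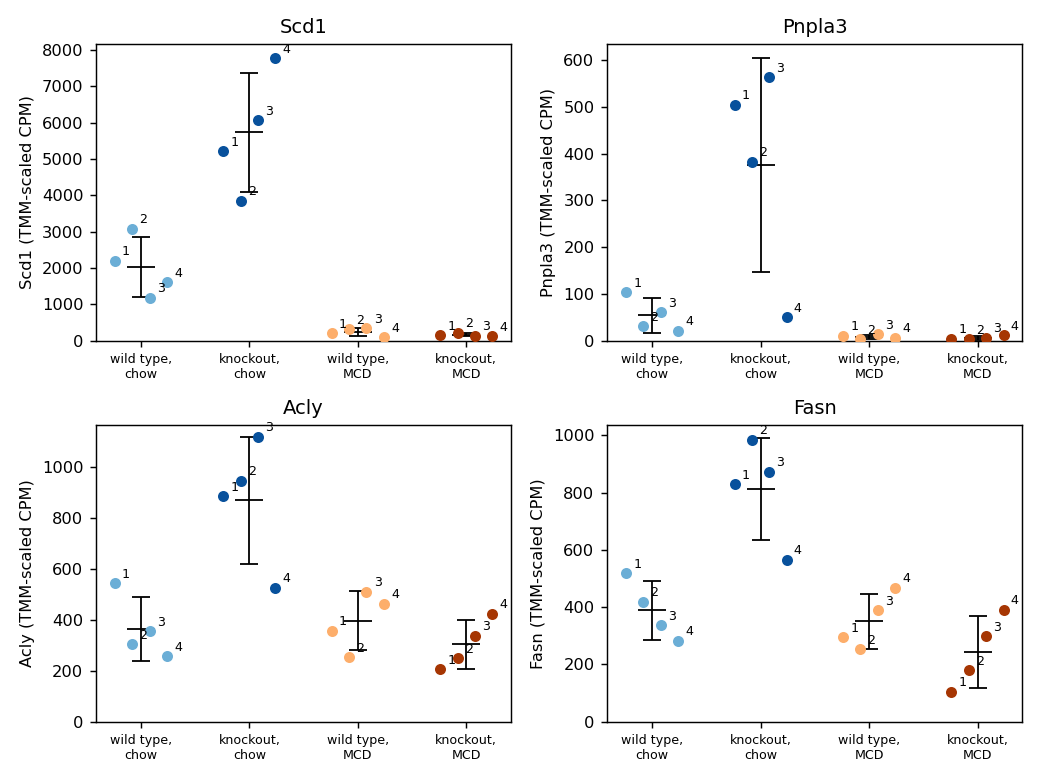
Scd1, Pnpla3, Acly and Fasn in TMM-scaled CPM (vertical axes) in each library, with library numbers, and the mean and SD of each group as a bar with whiskers. The chow-fed knockout libraries lie highest for Scd1, at 3853 to 7782 CPM against 1173 to 3081 CPM in the chow-fed wild type, while Pnpla3 in knockout chow library 4 (50.06 CPM) lies among the wild type.

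The fourth comparison asked what the loss of Tspo did on the MCD diet, where the series title places a difference in fibrosis. Matrix and stellate cell genes were lower as a group in the knockout (camera adjusted p = 0.000936, adjusted p = 0.747 with an estimated correlation), but this call depended on single libraries and on the index, as given below. Cholesterol synthesis genes were also lower as a group (adjusted p = 6.06e-06, adjusted p = 0.699 with an estimated correlation), and no single gene passed the threshold. Long transcripts were lower too (median -0.176, camera adjusted p = 7.17e-06) and short ones higher (median 0.488, camera adjusted p = 8.56e-07). Both had an adjusted p of 0.576 with an estimated correlation. Both shifts came from knockout MCD library 1, with list means of -0.36 (long) and 0.4 (short) relative to the wild type on chow. Long means were 0.56 to 0.92 in the other knockout and 0.62 to 0.92 in the wild-type MCD libraries. Short means were -1.11 to -0.74 and -1.02 to -0.59. With edgeR 0 of 11162 genes were called, and 81 had an unadjusted p under 0.05, where 558 would be expected by chance. With so few small p-values the test may have been too strict in this contrast, for a cause that was not tested. The 0 calls therefore do not show that the knockout had no effect on MCD. DESeq2 and limma-trend also called 0. On simulated counts with these group sizes, edgeR recovered 57 of 100 genes changed 2-fold and 92 of 100 changed 4-fold in this contrast. No simulated library stood apart from its group, so these shares may overstate what the real libraries could show. Tspo itself was not called here.

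Of 31 matrix and stellate cell genes 4 had log2 folds above 0, with 0 called and 0 adjusted over the list alone. The mean of the list, as log2 CPM relative to the wild type on chow, was 1.54 in wild-type MCD library 2 and 0.38, 0.42 and 0.49 in the other wild-type MCD libraries, against 0.17, 0.74, 0.61 and 0.56 in the knockout. Without wild-type MCD library 2 the list's direction turned upward (adjusted p = 0.141), and without knockout MCD library 1 it was not called (adjusted p = 0.232), nor with the index in the model (adjusted p = 0.825). Timp1 was at 17.8 ± 4.83 CPM in the wild type and 13.1 ± 2.68 CPM in the knockout (-0.44 ± 0.26 (adjusted p = 1)), and the gelatinase Mmp2 at 17.6 ± 7.82 and 12.8 ± 4.10 CPM. Of 23 cholesterol genes 1 had a log2 fold above 0, with a median of -0.28 and 0 adjusted over the list alone (adjusted p = 6.06e-06, adjusted p = 0.699 with an estimated correlation). Lss, the lanosterol synthase, was at 52.3 ± 33.1 and 30.8 ± 3.61 CPM. This list was not called without wild-type MCD library 1 (0.0551), wild-type MCD library 4 (0.054) or knockout MCD library 2 (0.135).

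**Figure D5:**
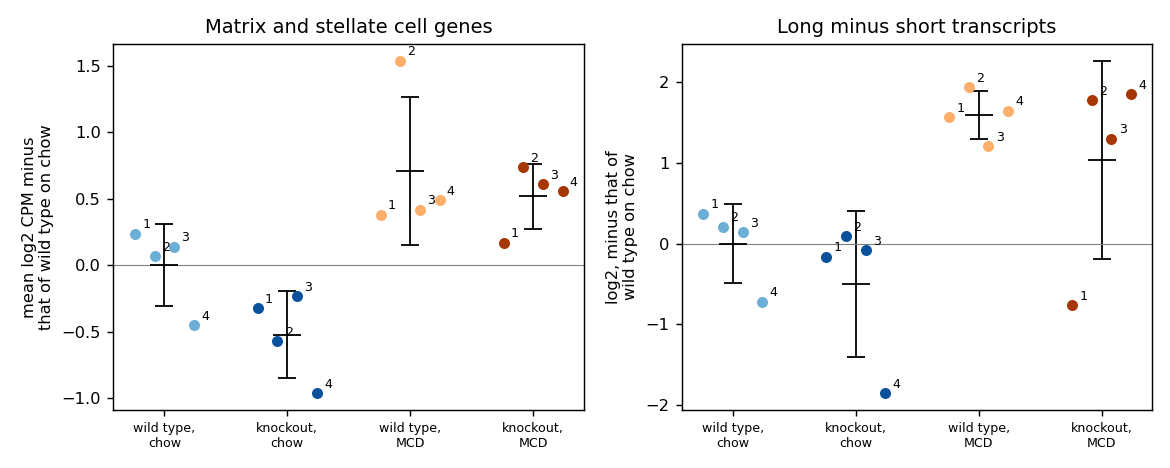
Mean log2 CPM of 31 matrix and stellate cell genes (left) and of long minus short transcripts (right) in each library, relative to the wild type on chow, with library numbers and the mean and SD of each group. Wild-type MCD library 2 lies highest for the matrix genes at 1.54, and knockout MCD library 1 lies among the chow libraries for the index at -0.76.

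Lipid droplet genes were higher as a group (adjusted p = 0.00371, adjusted p = 0.111 with an estimated correlation), with 15 of 16 folds above 0 and 0 called, also adjusted over the list alone. This list kept its call without any single library and lost it with the index in the model (adjusted p = 0.0579). The droplet protein Cidea was at 5.12 ± 1.48 CPM in the wild type and 7.45 ± 2.65 CPM in the knockout. The other 7 called lists each lost their call without at least 1 library and had 0 members called, also adjusted over the list alone. Fatty acid synthesis genes were lower (0.0101; adjusted p = 0.699 with an estimated correlation; 0.39 without wild-type MCD library 3, 0.361 without knockout MCD library 1, 0.0551 without wild-type MCD library 1 0.0538 without knockout MCD library 2 and 0.468 with the index in the model). Fatty acid oxidation genes were higher (0.0103; adjusted p = 0.699 with an estimated correlation; 0.265, 0.341 and 0.0682 without knockout MCD library 2, wild-type MCD library 4 and knockout MCD library 4). Macrophage genes were higher (0.0101; adjusted p = 0.699 with an estimated correlation; 0.064, 0.39 and 0.429 without wild-type MCD library 3, knockout MCD library 2 and wild-type MCD library 4). Lymphocyte genes were higher (0.0206; adjusted p = 0.462 with an estimated correlation; 0.115 and 0.182 without wild-type and knockout MCD library 4). Stress response genes were lower (0.0251; adjusted p = 0.699 with an estimated correlation; 0.0538, 0.619, 0.214, 0.13 and 0.185 without wild-type MCD library 1 or 4 or knockout MCD library 2, 3 or 4, and 0.0661 with the index in the model). Clock genes were lower (0.0163; adjusted p = 0.189 with an estimated correlation; 0.0541, 0.0762, 0.0681, 0.0613 and 0.124 without wild-type MCD library 1 or 4 or knockout MCD library 1, 2 or 4, and 0.221 with the index in the model). Oxidative phosphorylation genes were higher (0.035; adjusted p = 0.747 with an estimated correlation; 0.0546, 0.273 and 0.246 without wild-type MCD library 1, 2 or 4), and their direction turned without knockout MCD library 1 (0.725) and with the index in the model (0.43).

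The last comparison tested the difference itself, the diet effect in the knockout minus that in the wild type. As a group, fatty acid synthesis genes went lower with the diet in the knockout than in the wild type (camera adjusted p = 4.78e-12, adjusted p = 0.111 with an estimated correlation). Cholesterol synthesis (3.14e-06, adjusted p = 0.699 with an estimated correlation) and stress response genes (7.74e-05, adjusted p = 0.26 with an estimated correlation) had the same direction. No single gene passed the threshold with edgeR, which called 0 of 11162. An unadjusted p under 0.05 was found for 330, where 558 would be expected by chance. The test may thus have been too strict here too, so 0 calls do not show equal diet effects. DESeq2 called 1, and limma-trend called 0, or 1 without the filter on low values. On simulated counts edgeR recovered 17 of 100 genes changed 2-fold and 67 of 100 changed 4-fold in this contrast, again without libraries that stand apart.

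Of 18 fatty acid synthesis genes 2 had a difference above 0, with a median of -0.69, and 0 were called over all genes and 5 downward adjusted over the list alone (adjusted p = 4.78e-12, adjusted p = 0.111 with an estimated correlation). For Scd1 the difference was -2.07 ± 0.53 (adjusted p = 1), from levels of 2014 ± 825 and 231 ± 112 CPM in the wild type and 5729 ± 1645 and 157 ± 41.2 CPM in the knockout, on chow and MCD. For Acly it was -1.63 ± 0.43 (adjusted p = 1). Of 23 cholesterol genes 0 had a difference above 0, with a median of -0.45 and 0 called, also adjusted over the list alone (adjusted p = 3.14e-06, adjusted p = 0.699 with an estimated correlation). For the sterol demethylase Cyp51 it was -0.78 ± 0.47 (adjusted p = 1). Of 21 stress response genes 3 had a difference above 0, with 0 called, also adjusted over the list alone (adjusted p = 7.74e-05, adjusted p = 0.26 with an estimated correlation). For Fgf21, a hormone released by the liver under metabolic stress, it was -1.88 ± 0.74 (adjusted p = 1). These 3 lists kept their call without any single library. Each fold on chow in the third comparison shares the chow libraries with this one, so the lists are not independent between them.

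Genes around TSPO itself, the 25 of mitochondrial sterol handling and TSPO partners, were not called as a list in any comparison. On the MCD diet 5 rose and 4 fell in the wild type and 8 rose and 5 fell in the knockout, also adjusted over the list alone (adjusted p = 0.734 and 0.871). Dbi, which encodes the diazepam-binding inhibitor that binds TSPO, fell from 1197 ± 416 to 252 ± 48.3 CPM in the wild type and from 2295 ± 1686 to 343 ± 220.3 CPM in the knockout. The 2 libraries labelled knockout with doubtful Tspo raise the latter means, with 4811 CPM against 1223 to 1630 CPM in the other 3 on chow and 673.1 CPM against 224.7 to 240 CPM on MCD. Soat1, which esterifies cholesterol, rose in both genotypes (adjusted p = 0.000366 and 0.000136), from few counts on chow.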

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

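The tests of the chance splits of single contrasts and single lists and of the position of knockout MCD library 1, the list gaps, the counting and swap tests of Tspo and the clock test were chosen after the results were seen. The long and short gene lists were fixed before their values were seen, and the bounds on them after.

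Group means of each list, Tspo and the added indices were searched for a library far from the other 3 of its group, which chance gives in about 1 of 20 groups; 16 of 144 groups had one. Among 233 named genes 94 of 932 gene and group combinations (10.1%) had such a library, 31 of them in knockout chow library 4, 19 in knockout MCD library 1 and 13 in wild-type chow library 4, against 0 to 7 in the others. Tspo was at 4.417 CPM in the library labelled knockout on chow number 4, against 0.656 to 1.287 CPM in the other 3. The long minus short index was -1.85 in that library, against -0.16 to 0.09. A clock index (output minus morning genes) was -2.37 in wild-type chow library 4, against 0.57 to 0.91. As mean log2 CPM relative to the wild type on chow, knockout chow library 4 was also apart in methionine and choline metabolism (0.52) and heme synthesis (0.47). Knockout MCD library 1 was apart in lipoproteins (-0.82), stress responses (0.39), oxidative phosphorylation (0.01) and heme synthesis (0.05). Wild-type MCD library 2 was apart in matrix and stellate cells (1.54), neutrophils (0.57) and cell cycle (1.79). Wild-type chow library 4 was apart in lymphocytes (-0.54) and the clock (-0.7), wild-type chow library 3 in neighbouring pancreas and fat (-0.58) and knockout MCD library 4 in bile duct cells (1.44).

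The diet effect differed between genotypes by the interaction test in 6 lists with the preset correlation and in 0 with an estimated one. The adjusted p was 3.14e-06 for cholesterol synthesis, 4.78e-12 for fatty acid synthesis, 0.0236 for matrix and stellate cells, 0.0163 for endothelium, 0.0206 for NRF2 targets and 7.74e-05 for stress responses. Of these lists 2 were called upward and 4 downward. The median log2 fold of the diet was higher in the knockout than in the wild type for matrix (0.983 against 0.574) and endothelial genes (0.314 against 0.203). It was lower for NRF2 targets (0.076 against 0.177). At least 6 lists were called in 53 of 100 drawn regroupings of genotype within diet, with up to 14, so chance is not excluded for this count. The matrix, endothelial and NRF2 calls were each lost without single libraries of both genotypes, among them knockout chow library 4 (adjusted p = 0.398, 0.0607 and 0.0651).

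Chance was argued against for the diet counts, where 1 of 35 is the smallest share the splits can give. Of 35 splits of the 8 wild-type libraries 1, the real one, gave as many as 3809 genes, and the highest other gave 1. Of 35 splits of the knockout libraries 1 gave as many as 4514, and the highest other, which exchanged knockout MCD library 1 for a chow library, gave 2085, which points to a structure of these samples. For genes moving the same way in both genotypes 1 of 100 pairs of splits reached 3052, and the highest other gave 0. As no other wild-type split called more than 1 gene, this was nearly fixed in advance and adds nothing to the counts. Chance was not excluded for the knockout count on chow (2 of 35 splits gave at least 1 gene, the highest other 286), and a split with 286 genes points to a structure of these samples. The real counts of 0 for the knockout on MCD (highest other 2) and the interaction (highest other 3) are reached by any split, 35 of 35 and 100 of 100, so the splits cannot test them. Chance was not excluded for the number of lists called: 10 of 35 splits gave at least 9 for the diet in the wild type (highest other 13), 12 of 35 at least 9 in the knockout (16), 12 of 35 at least 7 for the knockout on chow (15) and 6 of 35 at least 10 on MCD (14). List by list, with the preset correlation, 1 of 35 splits, the real one, gave a camera p as small for lipoproteins in each genotype, red blood cells in the wild type, heme synthesis on chow, and lipid droplets and lymphocytes on MCD, and 3 of 100 did for fatty acid synthesis in the interaction. For the other called lists it was 2 to 23 of 35 and 6 to 60 of 100, with 15 of 35 for cholesterol synthesis on MCD (p real 4.6e-07, smallest other 1.3e-68), 23 of 35 for matrix genes on MCD, and 19 of 100 for cholesterol synthesis in the interaction.

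The diet effect came with higher long and lower short transcripts. The medians of the long and short lists were 1.435 apart on the log2 scale in the wild type and 1.873 in the knockout, as a trend with message length or RNA quality would give, though the short list is mostly ribosomal and respiratory genes and lengths were not measured. With the index as a covariate 2077 of the 3809 wild-type calls (54.5%) were called as well. This met the bound written beforehand against such a trend as the whole cause. In the knockout, for which no bound was written, 2254 of 4514 calls (49.9%) were kept. The index only stands in for message length and follows the diet in most libraries, so the calls kept cannot exclude the trend. The calls lost leave the trend open for the other genes. Knockout MCD library 1, whose index was that of chow libraries, lay at 0.793 of the way from chow to MCD on the 3809 wild-type calls. On the 1877 of them under 2-fold it lay at 0.594, and 1 library excludes nothing. A part of the effect may thus follow RNA quality, and the diet itself stays open for the same genes because the index is confounded with diet in the other libraries.

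Tspo in knockout chow library 4 and knockout MCD library 1 lay above the other 3 libraries of each group. It lay inside the wild-type range on chow and below the wild-type range on MCD. The same libraries had the lowest long minus short index of their groups (-1.85 and -0.76). Whether their Tspo level goes with this index, and so with RNA quality, was not tested and stays open. Counting noise was argued against, since the lower Poisson bound was at least 2.453 times the mean of the other 3 libraries, and so was an exchange of libraries within a diet, since 0 wild-type libraries had Tspo at a knockout level. A single wrong label cannot be told apart from a real difference for knockout chow library 4, whose fatty acid synthesis mean (0.09) lay in the wild-type range of -0.23 to 0.36 but whose Scd1 (7782 CPM) lay above it (1173 to 3081 CPM). A scale from wild type (0) to knockout (1) was set on 513 genes that part knockout from wild-type libraries 1 to 3 on chow. Knockout chow library 4 lay at 1.158 on it. It differed from wild-type chow library 4 in the knockout direction on 363 of these genes (70.8%). Wild-type chow library 4 itself lay at 0.931, so these genes did not place it by its genotype label. The difference of 0.227 met the bound written beforehand for a wrong label, but it was set aside for this reason, a rule added after the value was seen, and residual or mixed tissue was not tested.

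Fatty acid synthesis genes were higher in the chow-fed knockout, for which loss of Tspo stays open as the biological explanation. The list was still called by camera without the 3 libraries that stand apart (adjusted p = 6.38e-07 with the preset correlation). With all libraries it was not called with an estimated correlation (adjusted p = 0.213). Knockout chow library 4, at a list mean of 0.09, lay below the other knockout chow libraries, so leaving it out could only widen the difference. The call without the 3 libraries therefore says only that the difference is present in chow libraries 1 to 3. Chance could not be excluded: 3 of 35 splits gave a camera p as small as the real 5.97e-09, and the smallest other was 3.33e-14. The time of sampling may also contribute and cannot be told apart, since the clock index was 1.32 to 2.65 in knockout and 0.57 to 0.91 in wild-type chow libraries 1 to 3, and -1.74 and -2.37 in their numbers 4. The list mean was 0.79 to 0.98 in knockout chow libraries 1 to 3 and 0.09 in number 4, against -0.14 to 0.36 and -0.23 in the wild type, while in the 8 MCD libraries the list and the index had a Spearman rho of 0.167 (exact permutation p = 0.703; Pearson r of -0.168, and 0.44 without the 2 farthest libraries).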

How the results depend on the processing

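The fits without chosen libraries, with library weights and with the long minus short index were chosen after the data were seen. The diet counts and their overlap were within 1.5 times the values in the report in all alternatives but the following, and no named gene past the threshold turned its direction in any. Against an absolute log2 fold of 0.5 the diet counts were 1593 (wild type) and 2176 (knockout), by construction of a stricter test, and with the index in the model the knockout count was 2886. For 247 gene and contrast pairs called in the report, 200 were called with the index in the model and 235 to 247 in the other alternatives that tested all of them, apart from the test against a log2 fold of 0.5, for which these pairs were not counted. With a block on the library number (replicate block) the counts were 3655, 4238, 1, 0 and 0 for the 5 contrasts, 2893 genes moved the same way in both genotypes, 44 lists were called, and Tspo was at -1.27 on chow and -2.15 on MCD. Tspo rests on 6 to 162 counts per library. The cause of the following changes was not tested, apart from the fewer libraries or the stricter test where those are named.

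The knockout count on chow (1) was 23 with DESeq2, 0 with only the compared groups, 7 without number 4 of every group, 2 with each of the limma-trend settings, 0 against the log2 fold of 0.5 and 3 with the index. It was 4 without knockout chow library 4 and knockout MCD library 1, 12 without both chow libraries numbered 4, 514 without these 3 libraries and 239 with library weights. The knockout count on MCD (0) was 1 without the first pair, 1 without the 3 libraries, 2 with library weights and 1 with the index. The interaction count (0) was 1 with DESeq2, 1 without number 4 of every group, 1 with limma-trend and no filter, 1 without the first pair, 4 without the 3 libraries and 5 with library weights. Tspo passed the threshold on chow without the first pair (-2.041), without the 3 libraries (-1.926) and with library weights (-1.914), with adjusted p from 0.00511 to 0.0107 there and from 0.0589 to 0.764 in the other alternatives. On MCD it passed in the same fits (-2.678, -2.676 and -2.514) and with the index (-2.665), with adjusted p from 9.8e-06 to 0.000349 there and from 0.0783 to 1 in the others. The libraries of the first pair were doubted for their high Tspo, so fits without them widen the Tspo difference by construction. Without the 3 libraries the diet calls of matrix (0.0525), bile duct (0.0942) and sex-biased genes (0.0596) in the wild type and of bile duct genes (0.0834) in the knockout were lost, as were stress response (0.0624) and heme synthesis (0.107) on chow and fatty acid synthesis (0.469), matrix (0.327) and lymphocyte genes (0.0525) on MCD. The 41 list calls became 0 with an estimated correlation. With fry 20 lists were called, 8 for the diet in the wild type and 12 in the knockout. Not all of these 20 were among the 41: neutrophil genes in the knockout had an adjusted p of 0.0314 with fry and 0.481 with camera. In the knockout contrast on MCD the oxidative phosphorylation list turned its direction without the first pair (adjusted p = 0.644), without the 3 libraries (0.583), with the index (0.43) and without knockout MCD library 1 (0.725), and the matrix and stellate cell list without wild-type MCD library 2 (0.141).

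With each library left out in turn the diet counts ran from 2827 to 4559 (wild type) and 3347 to 5333 (knockout), the overlap from 2375 to 3403 and the list calls from 33 to 46. The knockout count on chow ran from 0 to 15, that on MCD from 0 to 1 (1 without knockout MCD library 3), and the interaction count stayed at 0. The adjusted p of the knockout contrast on MCD ran from 3.15e-06 to 0.232 for the matrix and stellate cell list and from 0.0017 to 0.725 for oxidative phosphorylation. Tspo ran from -2.041 to -0.94 on chow and from -2.679 to -1.855 on MCD.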

Other observations

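The tests of the growth hormone and glucocorticoid lists at the end of this part were chosen after values of several members were seen. Bile acid transport and synthesis genes moved both ways on the MCD diet: of 21, 4 rose and 5 fell in the wild type and 4 rose and 7 fell in the knockout (4 and 7, and 4 and 8 adjusted over the list alone). The export pump Abcc3 rose from 4.17 ± 1.35 to 30.2 ± 12.7 CPM in the wild type, and Slc10a1, which takes bile acids up from blood, fell from 748 ± 152 to 176 ± 56.5 CPM. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose from 60.4 ± 31.8 to 287 ± 66.8 CPM. Of 18 acute phase genes 2 rose and 8 fell in the wild type and 3 rose and 9 fell in the knockout (3 and 8, and 4 and 9 adjusted over the list alone). The protease inhibitor A2m rose from 13.3 ± 5.22 to 166 ± 38.9 CPM, while Saa4 fell from 1418 ± 118 to 541 ± 61.4 CPM. Of 21 stress response genes 4 rose and 3 fell in the wild type and 4 rose and 6 fell in the knockout. In the wild type the asparagine synthetase Asns rose from 2.38 ± 1.48 to 34.1 ± 10.1 CPM. The endoplasmic reticulum gene Sdf2l1 fell from 45.7 ± 4.62 to 13.0 ± 2.30 CPM. Of 23 NRF2 target genes 7 rose and 4 fell in the wild type and 5 rose and 5 fell in the knockout (8 and 5, and 5 and 5 alone). Of 10 heme synthesis genes 0 rose in either genotype, 3 fell in the wild type and 4 in the knockout (alone, 1 rose in the knockout). None of these lists was called as a group for the diet (camera adjusted p = 0.122 to 0.635), and stress response counts were the same adjusted over the list alone.

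Immune and vessel lists were not called for the diet (camera adjusted p = 0.122 to 0.91). Counts adjusted over each list alone were the same unless given. Of 21 macrophage genes 6 rose and 2 fell in the wild type and 6 rose and 4 fell in the knockout. The tetraspanin Cd9 went from 2.53 ± 0.677 to 9.93 ± 1.36 CPM in the wild type. Of 12 lymphocyte genes 1 rose and 3 fell in the wild type and 1 rose and 2 fell in the knockout. Gzma, a granzyme of killer cells, fell from 3.76 ± 1.37 to 0.985 ± 0.298 CPM in the wild type. Of 5 neutrophil genes 1 rose in the wild type, and 2 rose and 1 fell in the knockout. Of 18 cytokine genes 3 rose and 3 fell in the wild type (3 and 4 alone) and 4 rose and 2 fell in the knockout. Of 22 interferon genes 2 rose and 3 fell in the wild type (0 and 2 alone) and 1 rose and 4 fell in the knockout. Bst2 of this list fell in the wild type from 254 ± 53.1 to 75.8 ± 11.5 CPM. Of 14 endothelial genes 3 rose and 1 fell in the wild type and 6 rose and 0 fell in the knockout. Cdh5, the junction cadherin of vessels, was at 5.39 ± 1.99 CPM on chow and 14.6 ± 2.29 CPM on MCD in the wild type. Cdh5 was not called with the long minus short index in the model (adjusted p = 0.294). Of 11 immediate early genes 3 rose and 2 fell in the wild type and 2 rose and 1 fell in the knockout. Of 12 clock genes 1 rose in the wild type (0 alone), and 1 rose and 2 fell in the knockout. Of 4 pancreas and fat genes 1 rose and 2 fell in each genotype (1 and 3 alone in the knockout).

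A hypothesis is that the diet lowers signalling through growth hormone and STAT5, since Igf1, Igfals and Prlr fell together. Of 13 measured genes of this axis 9 fell and 0 rose in each genotype, with median log2 folds of -2.29 and -2.16, and the list stood apart from all other genes with an estimated correlation too (larger camera p of both diet contrasts 2.99e-05). The list was drawn up after several of its members had been seen, so this is not independent evidence, and a lower content of hepatocyte transcripts may contribute. A second hypothesis, that glucocorticoid response genes were higher on the diet, stays open: 4 of 12 genes rose in each genotype and 2 fell in the wild type. The list mean was 0.34 to 0.86 in the 8 MCD libraries and -0.69 to 0.21 in the 8 chow libraries, but the list was not shown to stand apart from all other genes (larger camera p with an estimated correlation 0.481).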
